A study of Mus musculus with 6 samples.

How the data were processed

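RNA was taken from 6 samples labelled as mouse ESCs, 3 in BRD0705/PD03 and 3 in 2i, and libraries were made from total RNA with ribosomal RNA depletion, per the labels' protocols. The deposited tables give whole numbers for 53927 gene symbols per library. Salmon and the build mm10 are named in the submitters' processing notes, without a version of Salmon. Because Salmon gives estimated counts, the deposited whole numbers were taken as rounded estimated counts that the authors had not scaled between libraries. The annotation, the strand setting and the summing of transcripts to genes are not given in the sources used here. Estimated counts divide reads that fit several copies of a gene, so values of pseudogenes, paralogs and multicopy families are less certain than others.

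Groups and replicate numbers came from the sample titles. The labels name the line E14, and the growth protocol describes B6D2F1 ESCs, so the groups are compared as labelled without assuming which cells they are. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair within a group matched within sampling noise: over genes with at least 20 counts in the pair, chi-square per degree of freedom was 2.71 to 10.2. Totals ranged from 16968959 to 51180228 counts.

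Genes were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with filterByExpr, TMM scaling, robust estimation and group as the only term. Adjusted p-values are by Benjamini-Hochberg over 20422 genes, with a threshold of 0.05. The common biological coefficient of variation was 0.0591. Standard errors are the log2 fold change divided by the square root of the test's F. CPM use effective library sizes. Gene lists and chromosomes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and a variance trend, for sets of at least 4 genes, with Benjamini-Hochberg adjustment over lists or chromosomes. All tests were two-sided. Chromosome medians used genes with a mean of at least 1 CPM. Chromosomes and coordinates came from GENCODE M21 on GRCm38, matched by symbol: 51945 symbols matched 1 gene, 110 several and 1872 none.

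The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named 23 genes whatever their values, up to 4 members of each list past the threshold with the smallest p, and the 12 highest and 12 lowest log2 fold changes among called genes with groups that do not overlap and a mean of at least 5 CPM, leaving out gene models without a name. It named 154 genes, of which 152 passed the filter. A gene that the rule named is not reported here. A further 28 genes were named after their values were seen, and the text says so where they appear. Where a group had 0 counts, a fold is a bound against 3 counts over that group, and with 1 to 3 counts the ratio has an exact 95% interval.

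The steps were tested on simulated data for BRD0705/PD03 against 2i, over 20422 genes at the real depths. With the right sign, the test called 38% of 50 genes changed by 1.2-fold. It called 68% of 50 at 1.5-fold, 92% at 2-fold and 96% at 4-fold. Of its calls 8.30% were unchanged genes, a larger share than the threshold of 0.05 aims for. Camera called 10 of 10 lists of genes changed by 1.3-fold and 0 of 10 of unchanged genes. In the real data 61.4% of genes were called. The estimated correlation between genes was 0.70 in the fibroblast list and 0.72 in the nuclear respiratory chain list. The simulated rates were not tested under such conditions, so they may not carry over to the real data. The alternatives were DESeq2 1.42.0, median-ratio and upper-quartile factors, other filters, a test against a fold of 1.5, the replicate number as a block, leaving out each library, protein-coding genes only, omission of sex-chromosome genes, estimated correlations and fry. Added after the data were seen were lists without X-linked and Y-linked members, thinning to 16968959 counts, and a fibroblast gene covariate.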

Results

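RNA-seq of mouse embryonic stem cells (ESCs) was compared between 2 media, with 3 libraries in each group. Both media were serum-free N2B27 with PD0325901, an inhibitor of the kinase MEK, at 1 µM. The 2i medium also held CHIR99021, which inhibits both forms of the kinase GSK3, at 3 µM. The BRD0705/PD03 medium held BRD0705, an inhibitor selective for GSK3 alpha, at 8 µM. The comparison asks how the transcriptome of ESCs kept with the GSK3 alpha inhibitor differs from that of ESCs kept in 2i. The labels give the cell line as E14, an established male line, while the growth protocol tells of B6D2F1 ESCs derived and expanded on feeder cells separately in each medium, so the origin of the cells is not settled by the labels. The BRD0705/PD03 libraries held 31855685, 27825601 and 40790837 counts, and the 2i libraries held 16968959, 51180228 and 25026571. Values are CPM, counts scaled to a common library total, as mean ± SD with n = 3 per group, the value in BRD0705/PD03 given before that in 2i, and log2 fold changes of BRD0705/PD03 over 2i with their standard error. Coordinates are those of GRCm38, the assembly also called mm10.

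Libraries of BRD0705/PD03 held more RNA of genes of the formative and primed states, of Y-linked genes and of fibroblast markers (19 of 22 higher, median 0.93), and less RNA of several naive pluripotency genes and of most X-linked genes. With an estimated correlation the calls of the formative list (adjusted p = 0.602), the Y-linked list (adjusted p = 0.602), the fibroblast list (adjusted p = 0.687) and the X chromosome (adjusted p = 0.304) were lost. That version of camera rests on 4 residual degrees of freedom, so a call lost there does not show that a difference is absent. Fgf5, a marker of the early epiblast, stood at 10.4 ± 0.22 against 0.423 ± 0.167 CPM, and Lef1, a partner of beta-catenin in transcription, at 54.7 ± 2.21 against 2.63 ± 0.244 CPM. Tfcp2l1, a transcription factor of naive cells, stood at 423 ± 50.2 against 1314 ± 71.2 CPM, and Tbx3, another naive factor, at 33.4 ± 2.05 against 173 ± 6.45 CPM. The core factors moved little, with Pou5f1 at 687 ± 6.29 against 765 ± 54.9 CPM and Sox2 at 289 ± 7.64 against 300.4 ± 14.8 CPM. Of 20422 genes tested with edgeR, 6138 were higher and 6406 lower in BRD0705/PD03 at an adjusted p under 0.05, and 2223 were higher and 2098 lower by 2-fold or more. More genes were higher than lower with upper-quartile factors (6967 and 5689), without a filter (7047 and 6719), with a mean of at least 1 CPM (5549 and 5492) and without 2i replicate 1 (5921 and 5916) or 2 (5963 and 5863). The groups did not overlap for 13482 genes (66.0%), where chance alone gives 10%. The groups separated along the leading principal component, which held 83.1% of the variance, and log2 CPM values correlated across genes at 0.986 to 0.991 within groups and 0.916 to 0.924 between them. Tested against a fold of 1.5, 2498 genes were higher and 2596 lower. With the level of 5 fibroblast genes as a covariate, chosen after the data were seen, 2357 were higher and 2959 lower. Of the named genes 31 lost their call with that covariate, and the median ratio of their standard errors, with the covariate over without it, was 2.99. Among them 6 reversed (Tmem92, mt-Nd5, mt-Nd6, mt-Nd1, H1f4 and Col1a1), and 10 had a log2 fold change over 1.5 times smaller (Gsk3a, Ctnnb1, Sp5, Id1, Dab2, Vim, Ftx, Col3a1, Dcn and Col12a1). The other 15 stayed within 1.5 times (Pou5f1, Apc, Gsc, Eif1ad, Zscan4f, Bub1, Cdt1, mt-Co1, H2ac4, H1f5, Rlim, Rps18-ps5, Rpl15-ps3, Kdm5d and Dnmt3l). Col1a1, Col3a1 and Dcn are among the 5 genes of the covariate, so the loss of their calls follows from how it was built.

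**Figure D1:**
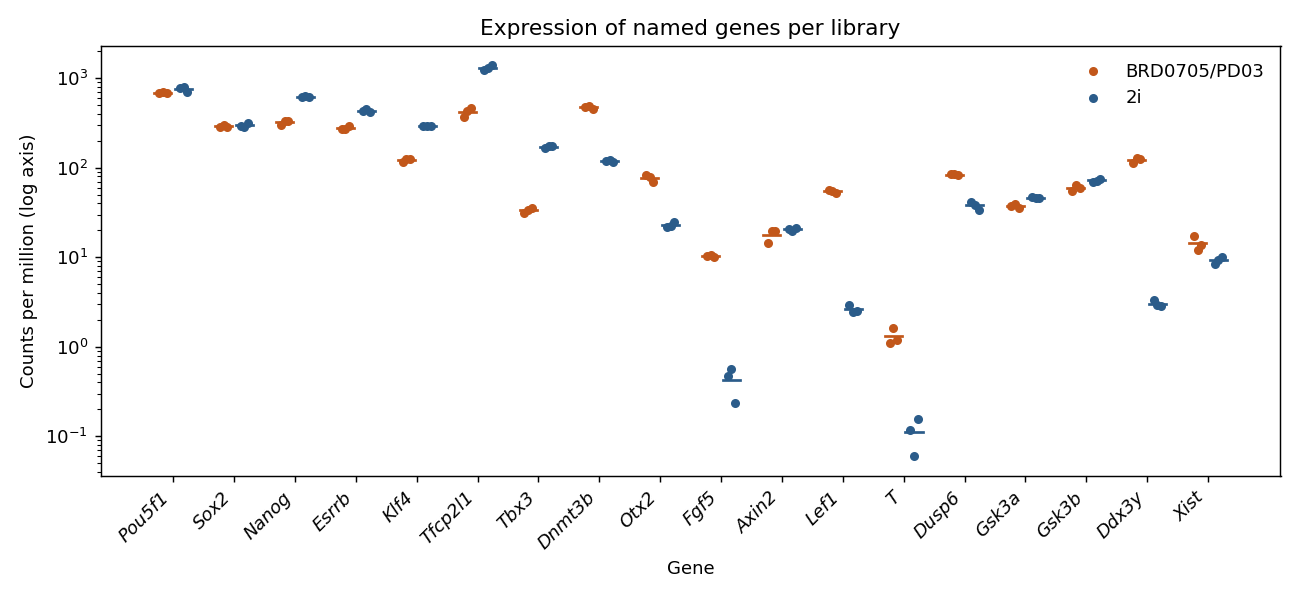
Expression of named genes in each library, in CPM on a log axis. Points are single libraries (3 per group) and horizontal bars are group means; Fgf5, Lef1 and Ddx3y lie higher in all BRD0705/PD03 libraries, and Tfcp2l1, Tbx3 and Nanog lie higher in all 2i libraries.

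The sex chromosomes separated the groups. Ddx3y, a Y-linked RNA helicase (chromosome Y, 1260771 to 1286629), stood at 122 ± 7.06 against 3.03 ± 0.26 CPM, Eif2s3y, a Y-linked translation factor gene, at 109 ± 3.0 against 1.16 ± 0.297 CPM, and Uty, a Y-linked homolog of a histone demethylase, at 84.1 ± 2.42 against 2.96 ± 0.555 CPM. Their log2 fold changes were 5.36 ± 0.07, 6.66 ± 0.09 and 4.86 ± 0.08, and every BRD0705/PD03 library lay above every 2i library. Of the Y-linked list, 6 of 6 tested members were higher (median 5.11, camera adjusted p = 0.00045, and adjusted p = 0.602 with an estimated correlation). Zfy1 had 3 counts over the 2i group, a ratio of 56.2 (95% interval 18.9 to 275). Kdm5d, named after its value was seen, differed far less, at 4.39 ± 0.299 against 3.29 ± 0.172 CPM. All Y-chromosome genes together took 1083 to 1209 CPM of library totals in BRD0705/PD03 and 634 to 771 in 2i, mostly from the gene model Gm47283 (chromosome Y, 90784738 to 90816464), named after its value was seen, at 757 ± 61.2 against 658 ± 54.5 CPM. Over 566 expressed X-linked genes, 410 were lower and 83 higher in BRD0705/PD03, with a median of -0.80 and quartiles of -1.25 and -0.16, so that the median X-linked gene stood 1.74 times higher in 2i. Medians of the 19 autosomes lay between -0.07 and 0.06. Camera called the X chromosome (adjusted p = 6.3e-13) and the Y chromosome (median 0.72 over 9 expressed genes, adjusted p = 0.00406) and 0 of 19 autosomes (0 at an unadjusted p under 0.05). With an estimated correlation neither was called, at adjusted p = 0.304 for X and adjusted p = 0.363 for Y. Mitochondrially encoded genes had a median of -0.19 over the 22 expressed genes of that chromosome.

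Xist, the RNA that coats an inactive X chromosome (chromosome X, 103460366 to 103483254), was low in both groups, at 14.4 ± 2.78 against 9.28 ± 0.752 CPM (0.63 ± 0.13, adjusted p = 0.00136). Tsix, its antisense partner, stood at 12.1 ± 0.268 against 6.06 ± 0.599 CPM. The 2 genes overlap and the strand setting of the counting is not given in the sources used here, so their reads cannot be separated with certainty. Ftx was lower at -0.84 ± 0.09 and Rlim, an X-linked ubiquitin ligase, at -0.19 ± 0.04. Of the 5 X-inactivation genes, 2 were higher and 2 lower (3 higher and 2 lower when adjusted over the list alone), with a median of 0.63 and an adjusted p of 0.838.

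**Figure D2:**
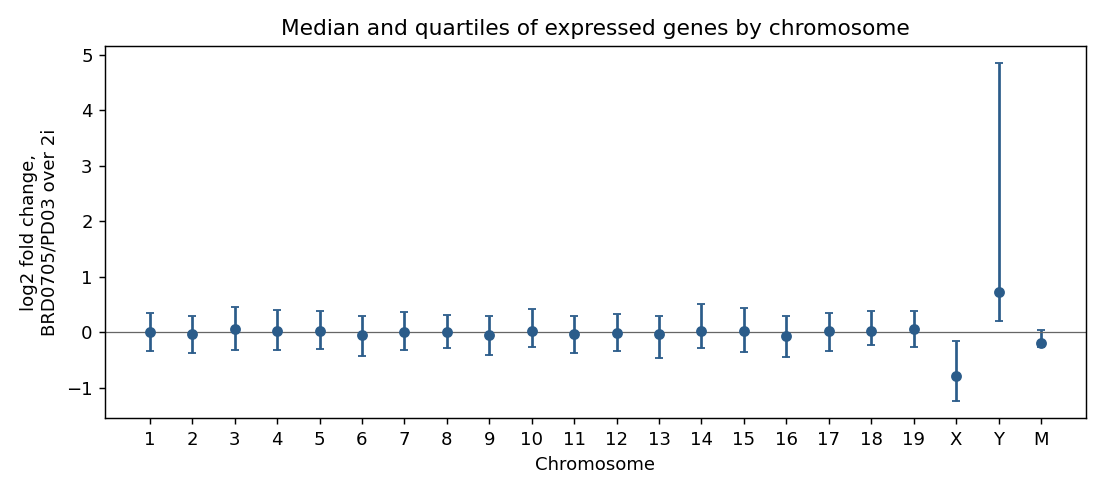
Log2 fold change of BRD0705/PD03 over 2i by chromosome. Points are medians over genes with a mean of at least 1 CPM and bars span the quartiles; the X chromosome lies at -0.80 and the Y chromosome at 0.72, while autosomal medians lie between -0.07 and 0.06.

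Counts of list members given here are over all genes tested, and the counts adjusted over the list alone were equal except where both are given. Of 30 lists fixed before the data were examined, 7 were higher and 2 lower by camera, and 0 of 30 were called with an estimated correlation (2 at an unadjusted p under 0.05). By fry, which asks only whether the members of a list move, 23 lists were called in a direction and 30 in either direction. Among lists that camera did not call, fry called naive pluripotency (adjusted p = 0.00073), LIF/STAT3 (0.00067), BMP/Smad1 (1.0e-05), germline (0.0165) and histone genes (0.0158) as lower. Wnt pathway components (0.00041), Nodal/Smad2 targets (9.9e-05) and the DNA methylation machinery (0.00237) were called as higher by fry. Other such lists are given below.

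Among naive pluripotency genes, 8 of 22 were higher and 14 lower in BRD0705/PD03, so the list moved both ways (median -0.31, adjusted p = 0.11). Nanog stood at 324 ± 20.3 against 625 ± 8.52 CPM (-0.95 ± 0.05), Klf4 at 122 ± 4.33 against 293 ± 2.67 CPM (-1.26 ± 0.04) and Esrrb at 279 ± 13.6 against 435 ± 12.6 CPM (-0.64 ± 0.04), all transcription factors of the naive network. Tbx3 (-2.37 ± 0.05) and Tcl1, a cofactor of the kinase AKT (-2.48 ± 0.05), fell further. Dppa3, a germ cell and early embryo factor, rose from 12.7 to 66.8 CPM (2.39 ± 0.06). Zfp42 (1.15 ± 0.04) and Prdm14 (-1.36 ± 0.05), both named after their values were seen, moved in opposite directions. Among general pluripotency genes, 10 of 14 were higher and 3 lower (median 0.31, adjusted p = 0.0084, and adjusted p = 0.687 with an estimated correlation). Lin28a, which binds let-7 precursor RNAs, stood at 381 ± 14.7 against 35.3 ± 1.07 CPM (3.44 ± 0.05), Utf1 rose by 1.41, Zfp281 by 0.57 and Sall4 by 0.44 on the log2 scale. Pou5f1 was lower by a small margin (-0.16 ± 0.05, adjusted p = 0.00866), a call lost without 2i replicate 1 (0.0736) or replicate 2 (0.0662), with upper-quartile factors (0.0740) and with the fibroblast covariate (-0.19 ± 0.15, adjusted p = 0.406), where the change was no smaller and its standard error larger, and Sox2 did not pass the test (-0.05 ± 0.04, adjusted p = 0.285).

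Genes of the formative and primed states were the list with the highest median among the pluripotency lists. Of 19 members, 16 were higher and 3 lower (median 1.81, adjusted p = 8.6e-07, and adjusted p = 0.602 with an estimated correlation). Without X-linked and Y-linked members the adjusted p was 2.1e-06. Fgf5 changed by 4.52 ± 0.18 (adjusted p = 8.6e-14) and Otx2, a transcription factor of the epiblast, by 1.75 ± 0.07 (adjusted p = 1.3e-10). The DNA methyltransferase genes Dnmt3a and Dnmt3b stood at 148 ± 8.52 against 28.9 ± 0.659 CPM and 477 ± 21.8 against 119 ± 3.92 CPM. Lin28b rose by 2.11 and Sox4 by 2.62. Fibroblast markers and X-linked genes differed between the same groups of libraries, with medians of 0.93 and -0.80. The formative genes named in this paragraph were not among the 31 named genes that lost their call with the fibroblast covariate. The list as a whole was not tested with that covariate.

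The transcripts of both kinases were slightly lower in BRD0705/PD03. Gsk3a (chromosome 7, 25228258 to 25237851) stood at 37.2 ± 1.83 against 46.4 ± 0.947 CPM (-0.32 ± 0.05, adjusted p = 2.5e-05) and Gsk3b (chromosome 16, 38089001 to 38246084) at 59.7 ± 4.23 against 72.1 ± 2.37 CPM (-0.27 ± 0.05, adjusted p = 0.00015). Ctnnb1, which encodes beta-catenin, differed by 0.10 ± 0.04 (adjusted p = 0.0401), and lost the call without BRD0705/PD03 replicate 2 (adjusted p = 0.139) or replicate 3 (adjusted p = 0.115) and without genes of the sex chromosomes (0.09, adjusted p = 0.0659). Axin2, a feedback target of beta-catenin, did not pass the test at 17.9 ± 3.04 against 20.5 ± 0.954 CPM (-0.19 ± 0.11, adjusted p = 0.191), but passed as lower with libraries thinned to equal totals (-0.21, adjusted p = 0.0459) and with the fibroblast covariate (-0.86, adjusted p = 0.0102). With that covariate Gsk3a (-0.18, adjusted p = 0.455), Ctnnb1 (0.05, adjusted p = 0.834) and Sp5 (0.60, adjusted p = 0.438) were not called. Other targets rose, among them Lef1 (4.41 ± 0.08, adjusted p = 8.5e-19), Sp5 (2.81 ± 0.516 against 1.07 ± 0.00614 CPM), the mesoderm factor T, also called brachyury (1.32 ± 0.28 against 0.112 ± 0.0493 CPM), the cyclin gene Ccnd1 (0.79 ± 0.04) and Ndrg1 (1.17 ± 0.06). Apcdd1, an inhibitor of Wnt signalling, fell by 1.71 on the log2 scale. Cdx1 (-3.34 ± 0.32) and Notum (29.8 against 59.8 CPM), named after their values were seen, were also lower. Cdx2 was below the filter on low counts, at 0.163 ± 0.0492 against 0.357 ± 0.142 CPM. Of 21 tested targets, 13 were higher and 4 lower (median 0.71, adjusted p = 0.0474, and adjusted p = 0.822 with an estimated correlation). That call was also lost without BRD0705/PD03 replicate 2 (0.0674), BRD0705/PD03 replicate 3 (0.0663) or 2i replicate 1 (0.0745), and with median-ratio size factors (0.0512). Without X-linked members the median was 0.75 and the adjusted p was 0.0518. That setting also left the Y-linked and X-inactivation lists out of the adjustment, so its loss of the call cannot be credited to X-linked targets. Among Wnt pathway components, 12 of 24 were higher and 8 lower (median 0.14, adjusted p = 0.527). The receptor gene Fzd7 rose from 24.3 to 154 CPM (2.66 ± 0.05) and Fzd2 by 2.17, Apc differed by 0.38 ± 0.04, and the X-linked Amer1 by -0.60 ± 0.06.

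Genes that report on ERK, the kinase downstream of MEK, were higher as a group. Of 19 members, 14 were higher and 3 lower (median 0.58, adjusted p = 0.00562, and adjusted p = 0.669 with an estimated correlation). Dusp6, an ERK phosphatase gene, stood at 83.7 ± 0.855 against 38.2 ± 3.7 CPM (1.14 ± 0.06), and the immediate early genes Egr1 and Fos rose by 2.19 and 1.99. Spry4, a feedback inhibitor, went the other way at 4.15 ± 0.277 against 7.53 ± 0.443 CPM (-0.86 ± 0.11), as did Etv4, named after its value was seen (0.958 ± 0.441 against 47.6 ± 2.94 CPM). LIF/STAT3 targets moved both ways, with 7 higher and 6 lower of 14 (adjusted p = 0.829), a median of 0.16, and a mean of -0.21 with the direction of the test. Pim1 (-1.14 ± 0.05), Jak3 (-1.23 ± 0.06) and Bcl3 (-1.90 ± 0.12) fell. Of 11 Nodal/Smad2 targets, 7 were higher and 2 lower (median 0.25, adjusted p = 0.068), and the list passed without BRD0705/PD03 replicate 3 (0.0482) or 2i replicate 2 (0.0481). Lefty1, a Nodal antagonist, stood at 162 ± 20.1 against 23.6 ± 0.801 CPM and Skil at 315 ± 10.1 against 113 ± 3.02 CPM, while the receptor gene Acvr1b differed by -0.48 ± 0.06. Of 10 BMP/Smad1 targets, 4 were higher and 4 lower (median 0.08, mean -0.31 with the direction of the test, adjusted p = 0.81). The X-linked phosphatase gene Dusp9 stood at 14.6 ± 1.21 against 111 ± 2.76 CPM (-2.94 ± 0.06), Smad6 fell by 2.45 and Id4 by 0.70, and Id1 rose by 2.04.

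Lineage markers moved in both directions, and camera called none of these 5 lists. Fry, which does not compare a list with other genes, called the primitive streak (adjusted p = 0.00073), neural ectoderm (adjusted p = 1.0e-05), endoderm (adjusted p = 0.0307) and 2-cell-like lists (adjusted p = 0.0158) in a direction, with the endoderm and 2-cell-like lists lower. Of the primitive streak and mesoderm genes, 5 of 9 were higher and 2 lower (median 0.80, adjusted p = 0.499). Wnt3 stood at 2.41 ± 0.0455 against 0.139 ± 0.0713 CPM and Gsc at 0.402 ± 0.0689 against 1.64 ± 0.206 CPM, and Fgf8, with 2 counts over the 2i group, had a ratio of 48.1 (95% interval 13 to 402). Endoderm genes numbered 7 higher and 5 lower of 14 (median 0.17, adjusted p = 0.864). The laminin genes went apart, with Lama1 at 25.2 ± 0.613 against 159 ± 12.8 CPM, Lamc1 changed by -1.12 ± 0.04 and Lamb1 at 138 ± 10.9 against 38.6 ± 1.9 CPM; Dab2 differed by 1.01 ± 0.20. Gata6, a factor of primitive endoderm, did not pass the test (0.513 ± 0.0717 against 0.614 ± 0.148 CPM, adjusted p = 0.654). Of the neural ectoderm genes, 5 of 10 were higher and 4 lower (median 0.56, adjusted p = 0.203). Pax6, a neural and eye transcription factor, stood at 13.1 ± 0.242 against 0.363 ± 0.0969 CPM, and Ncam1, Sox11 and Map2 rose by 0.86, 0.72 and 0.94. Trophoblast genes numbered 7 higher and 4 lower of 13 (median 0.24, adjusted p = 0.641), and without X-linked members 5 and 4 of 11 (median -0.15, with the test still higher, adjusted p = 0.849). The keratin genes Krt8 and Krt18 rose by 3.18 and 2.63, while Gata3 stood at 0.39 ± 0.202 against 3.29 ± 0.394 CPM and Tead4 differed by -0.71 ± 0.06. Of 5 tested genes of the 2-cell-like state, 1 was higher and 2 lower (median -1.87, adjusted p = 0.597). Tmem92 (-3.13 ± 0.55) and Zscan4f (-2.02 ± 0.65, adjusted p = 0.0286) were lower, Eif1ad differed by 0.19 ± 0.05, and Zscan4c was below the filter, at 0.245 ± 0.0687 against 0.238 ± 0.0525 CPM. Zscan4f lost its call without BRD0705/PD03 replicate 3 (0.0831) or without 2i replicate 1 (0.0656), 2 (0.0615) or 3 (0.0886), and with the fibroblast covariate (-1.77 ± 2.82, adjusted p = 0.726), with which Tmem92 turned to 2.06 ± 1.93 (adjusted p = 0.494).

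Germline genes that DNA methylation keeps silent were 7 higher and 10 lower of 19 (median -0.48, adjusted p = 0.635). Without the X-linked members the median was 0.14, with 7 higher and 8 lower of 17 (adjusted p = 0.84). Dazl, a germ cell RNA-binding protein gene, stood at 7.63 ± 1.2 against 146 ± 1.44 CPM (-4.27 ± 0.07), and Hormad1 (-1.90 ± 0.07), Tex19.1 (-1.42 ± 0.04) and Rpl10l (-1.33 ± 0.06) also fell. Tdrd1, named after its value was seen, rose to 3.37 ± 0.0539 against 0.145 ± 0.0231 CPM. The DNA methylation machinery split evenly, with 6 higher and 6 lower of 14 (median -0.01, mean 0.11 with the direction of the test, adjusted p = 0.829). Dnmt3a and Dnmt3b rose as given above, Tet2, an enzyme that oxidises methylcytosine, fell by 1.63 and Zfp57, which protects imprints, by 0.52. Dnmt1 (0.04 ± 0.04, adjusted p = 0.466) and Dnmt3l (-0.23 ± 0.05) were named after their values were seen, and Dnmt1 passed as higher with upper-quartile factors (0.10, adjusted p = 0.00981). Imprinted genes were called higher, with 18 higher and 9 lower of 35 (19 and 9 when adjusted over the list alone), a median of 0.24, adjusted p = 0.039, and adjusted p = 0.669 with an estimated correlation. Without BRD0705/PD03 replicate 2 the adjusted p was 0.0593. Rian, a maternally expressed non-coding RNA of the Dlk1-Dio3 region on chromosome 12, stood at 1032 ± 50.1 against 187 ± 13 CPM (2.47 ± 0.05). Meg3, Mirg and Rtl1 of the same region, named after their values were seen, rose by 2.36, 2.54 and 2.87, where Rtl1 is overlapped by antisense transcripts. Dlk1, also named after its value was seen, did not pass the test (0.14 ± 0.39, adjusted p = 0.769). At 0.385 against 0.311 CPM it was barely detected, so a change like that of its neighbours cannot be judged from a call. Cdkn1c, a cell cycle inhibitor gene, stood at 14.6 ± 1.79 against 0.502 ± 0.0811 CPM, Peg3 at 681 ± 10.8 against 295 ± 7.33 CPM, and H19, also named after its value was seen, at 12.1 ± 0.783 against 1.5 ± 0.403 CPM. Plagl1 went the other way at 2.69 ± 0.388 against 87.5 ± 5.87 CPM (-5.02 ± 0.08).

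Cholesterol synthesis genes were lower as a group, with 3 higher and 18 lower of 24 (median -0.44, adjusted p = 0.00045, and adjusted p = 0.669 with an estimated correlation). Ebp (-1.79 ± 0.06) and Nsdhl (-1.36 ± 0.05), both X-linked, and Dhcr7 (-0.99 ± 0.05) encode late steps of the pathway. Hmgcs1, an early step, rose to 411 ± 5.68 against 122 ± 1.98 CPM. Without X-linked members the list kept an adjusted p of 0.00464, with 16 of 22 lower. Lysosome and autophagy genes (TFEB targets) were 3 higher and 15 lower of 25 (median -0.25, adjusted p = 0.0155, and adjusted p = 0.822 with an estimated correlation). That call was lost without X-linked members (median -0.16, adjusted p = 0.0705), where the adjustment also left out the Y-linked and X-inactivation lists. Lamp1 (-0.70 ± 0.04), Hexa (-0.83 ± 0.05) and the X-linked Gla (-0.93 ± 0.05) fell, while Rragd, a GTPase gene of nutrient sensing, rose by 1.33.

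Camera did not call the other metabolic and stress lists, of which fry called the amino acid and ER stress list (adjusted p = 0.0112) and the aryl hydrocarbon receptor and xenobiotic list (adjusted p = 0.00192) as lower. Glycolysis genes were 9 higher and 10 lower of 21 (median -0.03 with the direction of the test, mean 0.14, adjusted p = 0.966), with Pdk1 at 121 ± 7.41 against 32.7 ± 0.397 CPM, Eno3 and Pfkm raised by 2.75 and 0.95, and Hk1 at -1.18 ± 0.05. Mitochondrially encoded genes were 0 higher and 4 lower of 13 (median -0.21, adjusted p = 0.478). mt-Co1 differed by -0.31 ± 0.04, and mt-Nd5 (-0.27 ± 0.06), mt-Nd6 (-0.21 ± 0.07) and mt-Nd1 (-0.24 ± 0.07) by less, where mt-Nd5 and mt-Nd6 overlap on opposite strands. Calls were lost for mt-Nd1 without 2i replicate 1 (0.0965) or 2 (0.142), with upper-quartile factors (0.118) and with protein-coding genes only (0.0583), for mt-Nd5 without 2i replicate 2 (0.0544) or 3 (0.0935) and with upper-quartile factors (0.0536), and for mt-Nd6 without BRD0705/PD03 replicate 3 (0.0964) or 2i replicate 2 (0.0755), with upper-quartile factors (0.0874) and after thinning (0.0579). With the fibroblast covariate mt-Nd5 (0.10 ± 0.13), mt-Nd6 (0.18 ± 0.18) and mt-Nd1 (0.04 ± 0.18) turned direction and were not called. Nuclear respiratory chain genes were 11 higher and 11 lower of 27 (12 and 12 when adjusted over the list alone; median -0.03, adjusted p = 0.954, and median 0.02 without X-linked members), with the X-linked Cox7b (-0.96 ± 0.04) and Ndufa1 (-0.92 ± 0.06), Cox5a (-0.60 ± 0.04) and Sdhc (0.45 ± 0.05). Amino acid and ER stress genes were 4 higher and 12 lower of 23 (median -0.19, adjusted p = 0.199). Asns, asparagine synthetase, stood at 455 ± 32.5 against 965 ± 15.9 CPM and Hspa5, an ER chaperone gene, at 708 ± 31.5 against 1225 ± 71.2 CPM, and Sdf2l1 and Phgdh fell by 1.54 and 0.69. Xenobiotic response genes of the aryl hydrocarbon receptor list were 4 higher and 6 lower of 15 (5 and 6 when adjusted over the list alone; median -0.05, adjusted p = 0.644). Gstm1 (-1.09 ± 0.05), Nqo1 (-0.90 ± 0.05) and the paralogs Abcb1a (-1.15 ± 0.06) and Abcb1b (-0.75 ± 0.04) fell.

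Targets of p53 were 8 higher and 10 lower of 19 (median -0.10 with the direction of the test, mean 0.06, adjusted p = 0.94). Pmaip1, which promotes apoptosis, stood at 61.5 ± 0.558 against 12.5 ± 0.751 CPM, Aen rose by 0.58, and Sesn1 (-1.57 ± 0.06) and the X-linked Eda2r (-0.96 ± 0.04) fell. Cell cycle genes moved little, with 11 higher and 6 lower of 25 (median 0.08, adjusted p = 0.641). Bub1 (0.38 ± 0.04), Cdt1 (0.35 ± 0.04), Aurka (-0.43 ± 0.05) and Ccnb2 (-0.35 ± 0.04) were the members with the smallest p. Replication-dependent histone genes were 0 higher and 6 lower of 10 (median -0.19, adjusted p = 0.169), with H2bc4 (-0.59 ± 0.07), H2ac4 (-0.26 ± 0.05), H1f4 (-0.23 ± 0.05) and H1f5 (-0.20 ± 0.05).

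Fibroblast markers, fixed as a list because the growth protocol names feeder cells, were higher in BRD0705/PD03. Of 22 members, 19 were higher and 0 lower (median 0.93, adjusted p = 8.6e-07, and adjusted p = 0.687 with an estimated correlation). The contractile genes Acta2 and Tagln stood at 60.6 ± 3.38 against 10.3 ± 0.623 CPM and 63.5 ± 3.42 against 5.07 ± 0.801 CPM, S100a4 rose by 1.72 and Vim by 0.61. Matrix genes named after their values were seen included Col1a1 (142 ± 29.6 against 77.7 ± 1.96 CPM), Col3a1 (297 ± 60 against 127 ± 0.402 CPM) and Dcn (55.7 ± 8.82 against 29.4 ± 2.55 CPM). Fn1, also named after its value was seen, did not pass the test (-0.02 ± 0.05, adjusted p = 0.727), but passed as lower with the fibroblast covariate (-0.36, adjusted p = 0.0396). The mean log2 CPM of Col1a1, Col1a2, Col3a1, Lum and Dcn was 5.90, 6.16 and 6.50 in the BRD0705/PD03 libraries and 5.18, 5.24 and 5.20 in the 2i libraries. Library composition differed too. A chosen set of small non-coding RNAs (Rn7sk, Rn7s1, Rn7s2, Rmrp and Rpph1) took 2.14% to 2.72% of counts in BRD0705/PD03 and 1.32% to 2.04% in 2i. Of this, Rn7sk took 1.11% to 1.32% and 0.61% to 0.76%. Other small RNAs were not counted in that share. Mitochondrial transcripts took 0.96% to 1.01% and 1.17% to 1.19%.

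**Figure D3:**
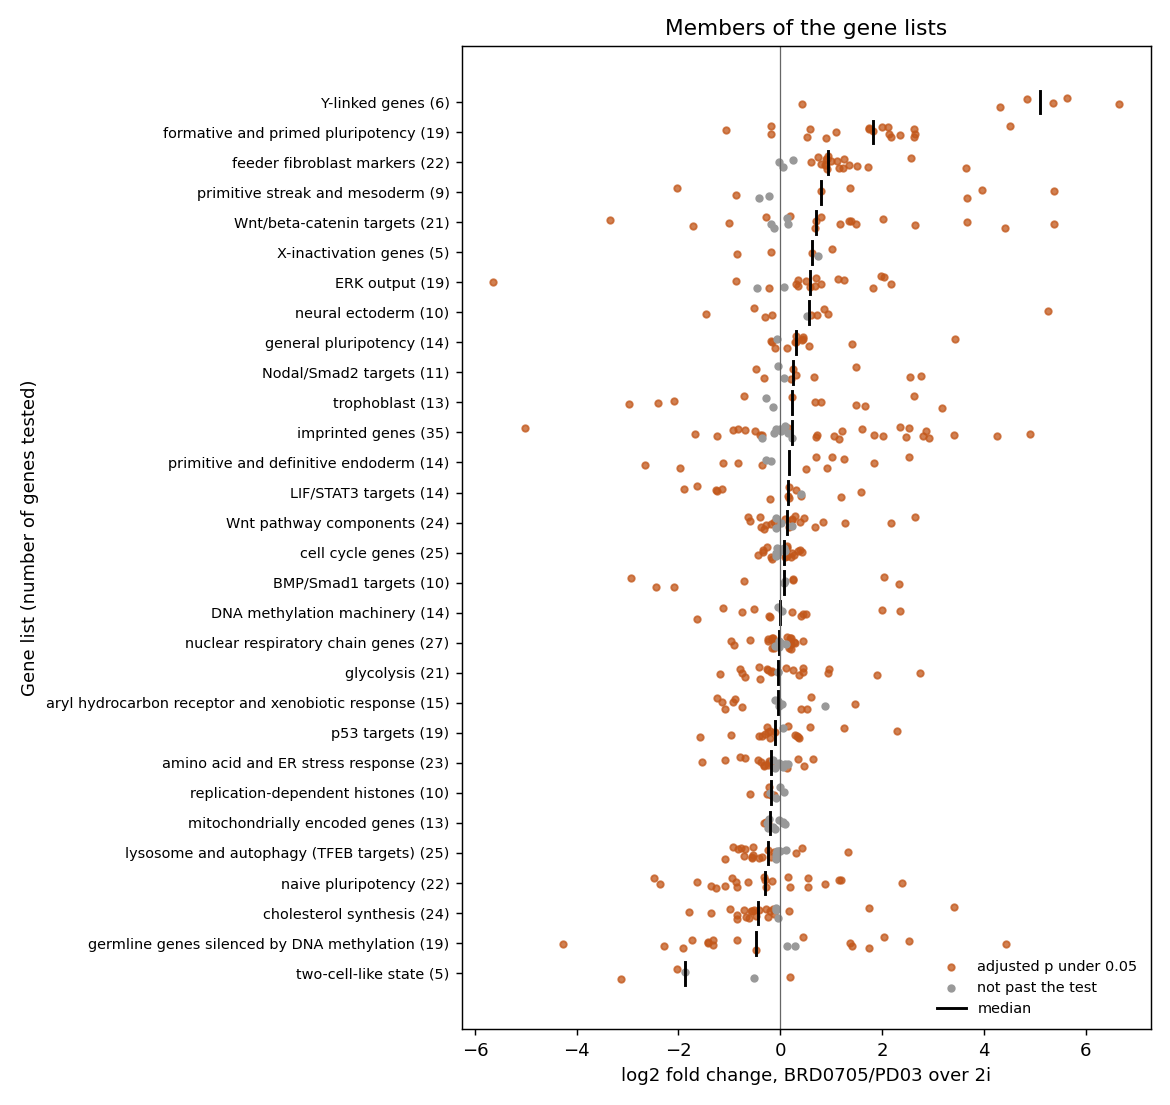
Log2 fold change of BRD0705/PD03 over 2i for the tested members of 30 gene lists, with the number tested in brackets. Points are genes, coloured where the adjusted p was under 0.05, and black bars are list medians; the Y-linked list has the highest median, 5.11, followed by the formative and primed list at 1.81.

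Several genes were close to all-or-none between the groups. Among the 12 genes with the highest fold changes, Nr1h5, a nuclear receptor gene, stood at 54.3 ± 7.1 against 0.053 ± 0.0502 CPM (chromosome 3, 102939658 to 102964133), Car4, a carbonic anhydrase gene, at 11.4 ± 1.25 against 0.0792 ± 0.0789 CPM, and Bcl11a, a transcription factor gene, at 22.4 ± 1.34 against 0.317 ± 0.0399 CPM. Vrtn, Slc8a3 and Frem2 differed by 6.65 ± 0.15, 6.53 ± 0.18 and 6.12 ± 0.10. Genes named or annotated as pseudogenes made up 5 of those 12. Rps2-ps13 stood at 563 ± 3.4 against 3.23 ± 0.444 CPM, Eif3s6-ps2 at 41.5 ± 1.26 against 0.469 ± 0.00887 CPM and Rps18-ps5 at 38.4 ± 13.8 against 0.574 ± 0.324 CPM, and Zfp42-ps1 had 1 count over the 2i group, a ratio of 2002 (95% interval 359 to 79104). Hist1h2al, annotated as a processed pseudogene, differed by 6.28 ± 0.15. Their counts are uncertain because reads can be shared with the parent genes. Eif2s3y, given above, completes the 12.

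Among the 12 lowest, 4 genes had 0 counts in every BRD0705/PD03 library, and their folds are bounds set by 3 counts over the group. Rpl15-ps3, a ribosomal protein pseudogene, was at least 6184-fold lower (chromosome 9, 22185607 to 22186221), Pramef17 at least 1162-fold, and the X-linked Xlr5a and Xlr5b at least 687-fold and 369-fold lower. With 1 or 2 counts over the BRD0705/PD03 group, the ratios of 2i over BRD0705/PD03 were 3131 (95% interval 562 to 123730.1) for Xlr4a, 1673 (95% interval 463 to 13823) for Xlr4b, 2240.3 (95% interval 619.8 to 18505) for Iqca, 604 (95% interval 167 to 4990.3) for Cd3g and 503 (95% interval 139 to 4157) for Stk33. Xlr3a stood at 0.479 ± 0.166 against 299 ± 5.92 CPM, Xlr4c at 0.039 ± 0.0479 against 21.1 ± 1.47 CPM and Pramel7 at 0.199 ± 0.111 against 61.3 ± 0.683 CPM. Xlr genes are near-identical X-linked copies, so the division of reads among them is uncertain. These intervals and bounds cover counting error only.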

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

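The fibroblast covariate, the thinning and the lists without sex-linked members were chosen after the data were seen. The count of 12544 changed genes stayed within 1.5 times under DESeq2 (11153), both scalings (12516 and 12656), both filters (13766 and 11041), thinning (11702), omission of sex-chromosome genes (11942), protein-coding genes only (10665) and each library left out (11656 to 12368). Replicate numbers did not pair the libraries, since deviations of same-numbered libraries correlated across genes at -0.04 to 0.03 and not every library correlated best with its own number, and the fit with the replicate block gave 12435. Of the called lists the block ended only the Wnt/beta-catenin target call (0.0526), and of the named genes those of Ctnnb1 (0.0563), Zscan4f (0.0607) and Col1a1 (0.0542). The test against a fold of 1.5 gave 5094 changed genes, 2498 higher and 2596 lower, because it asks for larger changes. The fibroblast covariate gave 5316, 2357 higher and 2959 lower. It raised the variance of the group term 8.88 times and left 3 residual degrees of freedom.

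With an estimated correlation 0 lists and 0 chromosomes were called. That version of camera rests on 4 residual degrees of freedom and has little power. Even the Y-linked list, with a median of 5.11, reached only an unadjusted p of 0.0401 by it. A call lost there does not show that a difference is absent. Adjusted p-values were 0.687 for general pluripotency, 0.602 for formative and primed pluripotency, 0.822 for Wnt/beta-catenin targets, 0.669 for ERK output, 0.669 for imprinted genes, 0.687 for feeder fibroblast markers, 0.669 for cholesterol synthesis, 0.822 for lysosome and autophagy (TFEB targets) and 0.602 for Y-linked genes. The chromosome X median of -0.80 and the chromosome Y median of 0.72 then had adjusted p of 0.304 and 0.363. Fry called 23 lists in a direction and 30 in either, since it does not compare lists with other genes. It reversed primitive and definitive endoderm (0.0307) and glycolysis (0.0804). Wnt/beta-catenin targets ranged from 0.0256 to 0.0745 with libraries left out, and were 0.0512 with median-ratio factors and 0.0518 without sex-linked members. Imprinted genes ranged from 0.0298 to 0.0593, glycolysis from 0.874 to 0.992 and nuclear respiratory chain genes from 0.703 to 0.975 with libraries left out. The setting without sex-linked members also left the Y-linked and X-inactivation lists out of the adjustment. By this the imprinted list, whose tested members are all autosomal, went from 0.039 to 0.0485. Without sex-linked members lysosome and autophagy stood at 0.0705, and the uncalled BMP/Smad1 targets (0.878), p53 targets (0.849), glycolysis (0.849) and nuclear respiratory chain genes (0.840) changed direction. The cause was not tested.

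Of 180 genes tested that the rule or a later choice named, 36 were no longer called against a fold of 1.5 and 31 with the covariate. Of those 31, 6 reversed, 10 had log2 fold changes over 1.5 times smaller and 15 stayed within 1.5 times. The median ratio of their standard errors, with the covariate over without it, was 2.99. Col1a1, Col3a1 and Dcn are part of the covariate. Log2 fold changes that reversed were 0.010 for Sox2 and 0.044 for Fn1 with upper-quartile factors. Fn1 also reversed to 0.0020 without a filter and 0.0018 with a mean of at least 1 CPM, and ranged from -0.073 to 0.028 with libraries left out, and Dlk1 from -0.030 to 0.56. With the covariate they were 2.06 for Tmem92, 0.10 for mt-Nd5, 0.18 for mt-Nd6, 0.040 for mt-Nd1, 0.10 for H1f4, -0.11 for Col1a1 and -0.061 for Dnmt1. The cause of these reversals was not tested. Thinning to the smallest total gave 11702 changed genes in place of 12544. Simulated 1.2-fold changes were called for 38% of 50 genes at the real depths, a share that may not carry over to the real data.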

Other observations

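The gene families, the genes named from them and the tests in this part were chosen after the results were seen, except the parent gene comparison and the regroupings of libraries. Genes were grouped into 469 families of at least 5 tested members by the stem of their symbols, leaving out Col4a3bp, a ceramide transfer protein gene, and Anxa11os, an opposite-strand RNA, and 5 families were higher and 5 lower by camera, and 0 with an estimated correlation (adjusted p = 0.985 for each, 6 of all families at an unadjusted p under 0.05). X-linked families expressed in germ cells or placenta were lower in BRD0705/PD03. All 9 Xlr genes were lower (median -9.22, or -8.93 with genes at 0 set at their bound, adjusted p = 4.6e-06), as were 5 of 5 Magea genes (median -7.75, or -6.88, adjusted p = 0.0452), 5 of 5 Fthl17 genes (median -4.23 either way, adjusted p = 0.0452) and 8 of 10 Rhox genes, with 2 higher (median -5.22, or -4.31, adjusted p = 0.0488). Rhox5 stood at 42.7 ± 0.928 against 524 ± 14.3 CPM and Fthl17f at 0.385 ± 0.205 against 7.59 ± 0.679 CPM, and Magea4, with 2 counts over the BRD0705/PD03 group, had a ratio of 2i over BRD0705/PD03 of 197 (95% interval 54.1 to 1633). The Pramel family, with 6 of 6 lower (median -4.20, adjusted p = 0.0421), has 1 X-linked member, and Pramel6 stood at 0.0611 ± 0.0118 against 13 ± 0.784 CPM.

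Families of matrix, membrane and cytokine genes were higher in BRD0705/PD03. Collagen genes were 25 higher and 3 lower of 35 (median 0.84, adjusted p = 0.00248), annexin genes 8 higher of 10 (median 0.99, adjusted p = 0.0333) and Pdlim genes, which encode adaptors of the actin cytoskeleton, 5 higher of 6 (median 1.35, adjusted p = 0.0452). Chemokine genes of the Cxcl family were 7 higher of 9 (median 0.90, adjusted p = 0.0452), and the interferon-induced Gbp genes 7 higher of 11 (median 0.88, adjusted p = 0.0452). Col12a1 stood at 128 ± 25.5 against 51 ± 1.68 CPM, Anxa11 at 45.9 ± 2.26 against 19.4 ± 0.213 CPM, Pdlim7 at 43.2 ± 2.77 against 10.6 ± 0.529 CPM, Cxcl12 at 12.7 ± 1.4 against 1.4 ± 0.411 CPM and Gbp4 at 14.6 ± 0.163 against 3.27 ± 0.396 CPM. Fibroblasts express collagen, annexin and Cxcl genes, and the fibroblast list was higher in the same libraries. Col1a1, Col1a2, Col3a1, Col5a1 and Col6a1 belong to both that list and the collagen family, so their calls are not separate observations.

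X-linked genes were lower and Y-linked genes higher in BRD0705/PD03. Loss of the Y chromosome alone from a male line would leave X-linked genes with the autosomes, and the X-linked median lay 0.73 below the lowest autosomal median (difference -0.73). More male feeder cells would raise Y-linked and fibroblast genes alike. The median of the 6 tested genes of the Y-linked list, 5.11, lay 4.18 above the fibroblast median of 0.93. Over the 9 expressed genes of the Y chromosome the median was 0.72, below the fibroblast median, so the comparison covers the listed genes only. A candidate explanation for the X-linked part is an extra active X chromosome in the cells of the 2i libraries, since the X-linked median was -0.80 with autosomal medians near 0, and Xist was low in both groups. Whether those cells also had no Y chromosome stays open. Of 9 Y-chromosome genes of at least 1 CPM in BRD0705/PD03, 4 stood in 2i at under 5% of that level. These were Ddx3y, Eif2s3y, Uty and Zfy1, at 1.07% to 3.52%, while the rest stood at 16.2% to 109%, with Kdm5d at 74.9% and Gm47283 at 87.0%. Y-chromosome genes together took 634 to 771 CPM in 2i against 1083 to 1209 in BRD0705/PD03. That total came mostly from Gm47283, so it is not separate evidence of a Y chromosome. Reads shared with X-linked copies were not analysed here, so the genes that stayed near their level do not settle the question. The dose of X-linked genes would then differ with the medium, so neither can be credited with any difference between these groups, and whether the cells were E14 or B6D2F1 stays open.

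Expressed in a single group (at least 5 CPM, and under 2% of that in the other) were 83 genes, 37 of them in BRD0705/PD03 and 46 in 2i. Processed pseudogenes were over-represented against protein-coding genes (odds ratio 13.3, exact 95% interval 7.81 to 22.2), which may point to a different genetic background of the cells in the 2 groups. The rule set for that explanation asked for both directions, and the odds ratio was 42.7 (20.3 to 93.7) for genes of BRD0705/PD03 but 2.74 (0.707 to 7.68) for genes of 2i. Only pseudogenes of the reference annotation could be counted, and copies absent from it would be missed. The excess in a single direction therefore does not argue against a different background. Reads moved between a pseudogene and its parent gene would make the parent change oppositely by 0.5 to 2 times as much. This held for 1 of 6 pairs (Rps2-ps13 and Rps2, exact 95% interval of the share 0.421% to 64.1%). Pairs were formed only where the symbol of the pseudogene held that of a tested gene. Pseudogenes with Gm symbols, and those named Eif3s6-ps, were therefore not covered. Rps18 also moved oppositely (-0.84, adjusted p = 1.6e-05), but fell by 211 CPM where Rps18-ps5 gained 37.8 CPM, outside that range. Past the threshold 3 of 6 parents changed the same way, and Rpl15 did not pass (-0.11, adjusted p = 0.0532). With 6 pairs and no sequence reads analysed here, the explanations cannot be told apart.

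Formative genes were higher and several naive genes lower in BRD0705/PD03, in the libraries whose fibroblast markers were higher (median 0.93), and the formative call was lost with an estimated correlation (adjusted p = 0.602). Lower beta-catenin output with the GSK3 alpha inhibitor would lower its targets. Their median was 0.71, with 13 higher and 4 lower of 21, so most moved the other way. The 4 lower were Apcdd1, Cdx1, Notum and Znrf3, and the feedback target Axin2 did not pass the test. Ccnd1 and Myc, both higher, belong to the ERK list as well. The camera call of the targets (adjusted p = 0.0474) was lost in several settings, which leaves lower beta-catenin output open. The ERK list also moved both ways, with 14 higher and 3 lower of 19. The bar for the targets counted all members and that for the ERK list only called members, both set after the data were seen. Higher ERK output in BRD0705/PD03 could go with the pattern, as the ERK list had a median of 0.58 and was called by camera, although the call was lost with an estimated correlation (adjusted p = 0.669), MEK inhibitor doses were equal and no cause follows from it. The medium is the biological difference the design names, and it stays open as untested apart from the sex chromosomes.

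The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 12544 changed genes and the highest other split 0, so 1 of 10 splits gave as many. For called lists the real split gave 9 and the highest other 8, and 1 of 10 gave as many. For called chromosomes the real split gave 2 and the highest other 2, and 4 of 10 gave as many. Each other split sets 2 libraries of a medium and 1 of the other against the reverse, so it holds part of the difference between media.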
